A study of Homo sapiens with 12 samples.

How the data were processed

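The data are peak lists from FoxK1 chromatin immunoprecipitation in HepG2 cells, 3 libraries after 20 min of 100 nM insulin and 3 without, all after 16 h without serum. Of the 12 samples, the 6 inputs have no processed file here and were not analysed. Groups and replicate numbers were taken from the sample titles and treatment labels.

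Per the submitters' processing notes, the tools were fastp, Bowtie2, SAMtools and MACS2 and the genome build was hg19; the notes used here give no versions, roles or order. Peaks were called by the authors on each library by itself, since the peak names in each deposited list carry one library's name. Whether the inputs served as control, and the threshold, are not given in the sources used here. The lowest deposited −log10 p lay between 3.00 and 3.01 in every list. The deposited fold of a peak is a linear ratio of its summit over the background that MACS2 estimated there. The deposited −log10 p and −log10 q depend on the depth of the library. The deposited score was within 1 of 10 times the −log10 p for 100% of the 223205 peaks. The deposited values themselves were used only to describe, rank or filter peaks within a list.

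Peaks of all 6 lists were merged into regions where they shared at least 1 bp, and a library has a region when any of its peaks overlaps it. Overlap of a pair of lists is the Jaccard index in base pairs. Peak numbers and covered length were compared by two-sided exact permutation tests over all 20 assignments. The overlap difference and the one-sided region counts were compared with the 10 splits of the libraries. Regions were named by a rule set at the same stage as the tests. It takes the 10 regions called in all 6 libraries with the highest mean within-list percentile of −log10 q, and the same 10 in each direction among regions called in 3 of 3 against 0 of 3. Coordinates are 1-based and in hg19. A region with several peaks of a library takes its strongest.

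The only annotation at hand was on another build, so 5 of the 10 planned results were not computed. These were the share of peaks at promoters, the genes with a promoter peak, the 27 gene lists tested for enrichment, the same lists compared between treatments, and the forkhead motif at summits. No gene names were assigned to peaks. Chromosomes other than 1 to 22 and X held between 73 and 163 peaks per list.

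The number of fragments at each summit and the background expected there were worked out from the deposited fold and −log10 p, taking the fold as (fragments + 1) over (background + 1) and the p as a Poisson upper tail. A single whole number of fragments met both within 0.0005 on the −log10 p scale (in proportion for values above 10) for at least 99.98% of the peaks of each list. The median summit had 27, 38 and 21 fragments in the insulin lists and 43, 35 and 22 in the untreated lists. These derived fragment and background values were also compared between lists, as descriptions of the libraries and not as a measure of binding. Peaks within 0.2% of a list's lowest background were taken as lying at that floor. On simulated data the procedure recovered 100% of 4830 whole summits and found a single whole number for 0.737% of 4344 summits that were not whole. The region step recovered all 618 insulin-only and all 236 untreated-only regions in a simulated set of 19826. Simulated regions were spaced so that neighbours never touched, so this checks the counting and not the merging of nearby peaks.

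Other settings fixed before the data were examined were each library left out in turn, only peaks with −log10 q of at least 5, lists of equal length, other definitions of a shared region, chromosomes 1 to 22 and X, and the replicate number as a block. Settings chosen after seeing the data left out replicate 3 in both treatments, with and without equal lengths, or chromosomes 2, 6, 14, 16, 17 and 20, left same-numbered pairs out of the overlap, or counted merged regions per library in place of peaks. Bins of 10 Mb were used where they held at least 10 regions called in all 6 libraries, which left 283. Those 6 chromosomes were the ones where regions of replicate 3 alone were more than 2 times as dense as on the median chromosome. Densities per 10 Mb of a chromosome are its regions divided by its number of 10 Mb bins with any region. A bin at a chromosome end counted as whole, so these densities are approximate. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.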

Results

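FoxK1, a forkhead transcription factor, was mapped by chromatin immunoprecipitation and sequencing in HepG2 cells, a human hepatocellular carcinoma line often used as a model of hepatocytes. Cells were kept without serum for 16 h and then received insulin (100 nM, 20 min) or no treatment. Each condition had 3 immunoprecipitated libraries, and 1 peak list was deposited for each of these 6 libraries. The 6 input libraries have no peak list here and were not analysed. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these libraries. Total read numbers are not given with peak lists, so the depth of each library is unknown. The comparison asks whether insulin changed where FoxK1 was bound.

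The insulin libraries held 48208, 45057 and 27503 peaks, and the untreated libraries held 44687, 31668 and 26082. The mean was 40256 ± 11156 (SD, n = 3) after insulin and 34146 ± 9547 (SD, n = 3) without it, a difference of 6110 peaks that was smaller than the spread within either condition (two-sided exact permutation p = 0.5, where 0.1 is the smallest value that 3 against 3 allows). The size of this difference rested on single libraries. It was 2134 without insulin replicate 1, 3710 without insulin replicate 2, 12487 without insulin replicate 3, 11381 without untreated replicate 1 and 2078.5 without untreated replicate 3. Peaks covered 26.0, 31.7 and 15.9 Mb in the insulin libraries and 28.2, 20.0 and 15.2 Mb in the untreated libraries (two-sided exact permutation p = 0.7, n = 3 each). The median peak was 431, 565 and 474 bp wide after insulin and 527, 528 and 478 bp wide without it. The authors' fold enrichment over background, a value of each list by itself, had a median of 5.95, 5.58 and 4.78 in the insulin lists and 4.65, 4.18 and 4.21 in the untreated lists. In both conditions replicate 3 had the fewest peaks, so part of the spread within each condition is a difference between replicate numbers. The insulin list was the longer of each same-numbered pair. A two-sided exact sign-flip test over these pairs gave p = 0.25, the smallest value possible with n = 3, so it cannot settle the question.

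Merging all peaks that overlapped by at least 1 bp gave 68127 regions of the genome (build hg19). Of these, 15887 (23.3%) were called in all 6 libraries and 23381 (34.3%) in a single library. The regions called in all 6 libraries had a median width of 1092 bp, against 335 bp for those of a single library. A region spans every peak merged into it, so part of this difference is given by construction. Shared sites were also the strong sites of every list. Of the 1000 peaks with the highest −log10 q in each list, between 99.7% and 100% lay in regions called in all 6 libraries. Within each list the median peak in a shared region stood at a percentile of −log10 q between 66.5 and 80.1, and the median peak found in that library alone at a percentile between 7.81 and 14.3.

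The shared site with the highest mean percentile of −log10 q was chromosome 17, 66452189 to 66454730. It ranked 1st or 2nd in each of the 6 lists, with a fold enrichment between 57.9 and 174. Next by mean percentile came chromosome 19, 41902683 to 41903963, with folds between 53.9 and 145 and no rank below 5. Chromosome 7, 106808095 to 106810684, had folds between 69.4 and 164 and no rank below 4. Chromosome 19, 30334867 to 30336691, reached the highest fold of any of these sites, 201, and its lowest was 59.2. Chromosome 17, 79366929 to 79368365, had folds between 36.6 and 100.5. At chromosome 16, 12070034 to 12070933, folds lay between 25.5 and 100.7. At chromosome 8, 95907247 to 95909299, they lay between 56.6 and 125. The other three of the 10 sites were on chromosome 2 at 54013440 to 54015582 and at 32502447 to 32503545, and on chromosome 20 at 42838727 to 42840076. All 10 of these sites ranked among the first 21 peaks of every list, insulin and untreated alike.

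Shared sites were densest on chromosomes 19 and 17. Chromosome 19 had 126 shared regions per 10 Mb bin with any region and chromosome 17 had 114, which is 2.54 and 2.30 times the median chromosome. Part bins at chromosome ends counted as whole, so the order of these 2 chromosomes is not firm. The background at peaks in the replicate 1 and 2 lists was also raised there, at 1.21 and 1.41 times the median chromosome. Chromosome X had 11.2 per 10 Mb, 0.227 times the median, and its background in those lists was the lowest of any chromosome, 0.567 times the median. In windows of 1 Mb, the highest number of shared regions was 39, at chromosome 17, 73000001 to 74000000. It was followed by 37 each at chromosome 14, 24000001 to 25000000, and chromosome 6, 26000001 to 27000000, a window that contains a large histone gene cluster. The 119 windows with 20 or more shared regions held 18.5% of them, while the median of the 2199 windows with any was 5.

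Within shared regions the median distance between the summits of a pair of libraries was between 24 and 42 bp. Between 56.6% and 75.8% of the summits of a pair lay within 50 bp of each other, and 12519 regions were called in all 6 libraries when regions were built from summits within 100 bp. The median distance averaged 33.8 bp over the 6 pairs of the same treatment and 33.2 bp over the 9 pairs of different treatment.

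Libraries of the same treatment did not overlap more than libraries of different treatment. The Jaccard index, the base pairs shared by a pair of lists divided by the base pairs covered by either, averaged 0.436 within treatments and 0.461 between them, a difference of -0.0249. Among the other 9 ways to split the 6 libraries into groups of 3, the difference was as high as 0.0813. That was for insulin replicates 1 and 2 with untreated replicate 1 against the rest, which puts both replicate 3 libraries on one side. Insulin replicate 1 and insulin replicate 2 had an index of 0.560, and insulin replicate 2 and untreated replicate 1 had 0.589, the highest of the 15 pairs. The lowest was 0.347, between insulin replicate 2 and untreated replicate 3. Without untreated replicate 1 the difference between the within-treatment and between-treatment means was 0.00107, the opposite sign, and without replicate 3 in both treatments it was -0.00536. Pairs that join a replicate 3 library to one of another number overlapped least (0.347 to 0.430). They were a larger share of the within-treatment pairs than of the between-treatment pairs. The negative difference therefore reflects this mix of pairs at least in part.

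**Figure D1:**
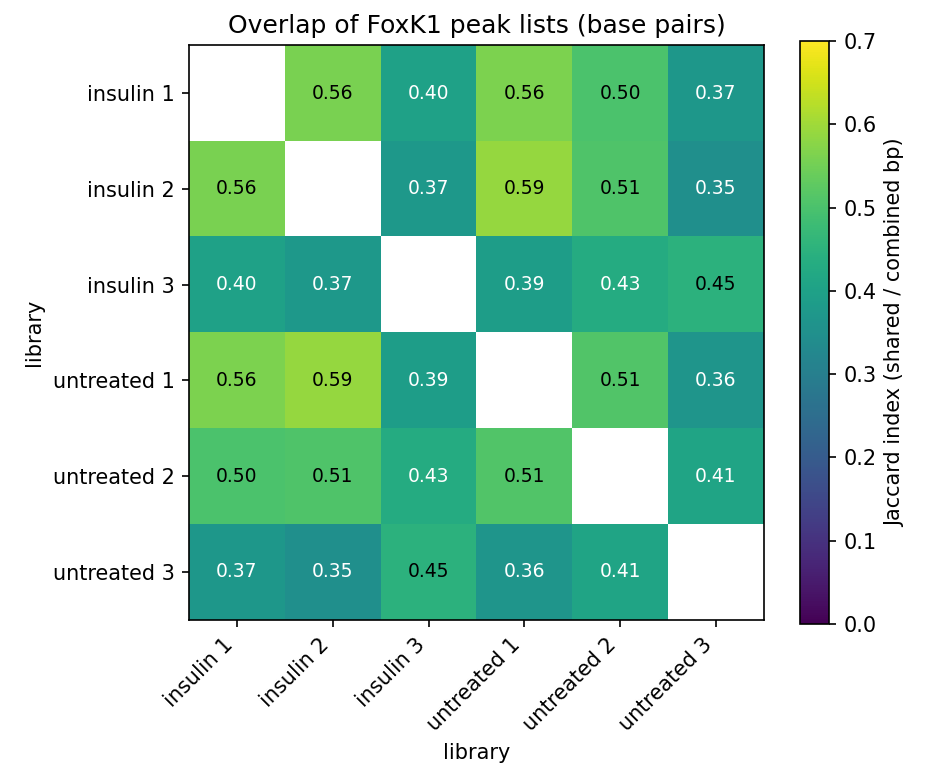
Heat map of the Jaccard index in base pairs for each pair of the 6 FoxK1 peak lists, with libraries on both axes and the index as colour and number. Insulin replicate 2 and untreated replicate 1 overlap most (0.589), and the pairs that join a replicate 3 library to a library of another number are between 0.347 and 0.430.

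Most regions found in at least 2 libraries of one treatment were found in at least 2 of the other. There were 36996 such regions after insulin and 29726 without it, and 27475 were common to both, which is 74.3% of the insulin set and 92.4% of the untreated set. A further 2848 of the insulin set were called in no untreated library, and 577 of the untreated set in no insulin library. The insulin lists were longer on average (40256 against 34146 peaks). These counts were not repeated with lists of equal length or for other splits, so the excess cannot be credited to insulin.

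Under the strictest rule, 256 regions were called in 3 of 3 insulin libraries and in none of the 3 untreated libraries, and 24 showed the reverse. The insulin lists were longer on average, however, although insulin replicate 3 (27503 peaks) was shorter than untreated replicates 1 (44687) and 2 (31668). With the 26082 strongest peaks of each list the counts were 104 and 83. This cut drops the weakest peaks of the longer lists, where most of the 256 regions stood, so it cannot settle why 256 exceeds 24. With only peaks of −log10 q of at least 5 the counts were 127 and 1. The −log10 q depends on the depth of the library, so this filter cannot settle it either. Leaving out 1 library makes the rule easier to meet, so a rise in both counts follows from the rule whichever library it is. The 256 rose to between 385 and 2382, most without insulin replicate 3. The 24 rose to between 30 (without insulin replicate 3) and 367 (without untreated replicate 3). The real split of the libraries gave 280 one-sided regions in all, and the highest of the other splits gave 4030. With lists of equal length these totals were 187 and 902. The highest split put both replicate 3 libraries on one side, while the real split keeps them apart. Other splits that keep them apart gave between 196 and 282, and between 156 and 278 with lists of equal length. A single region found in 3 of 3 against 0 of 3 libraries has an exact p of 0.1 at best, so no single region can be called changed.

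**Figure D2:**
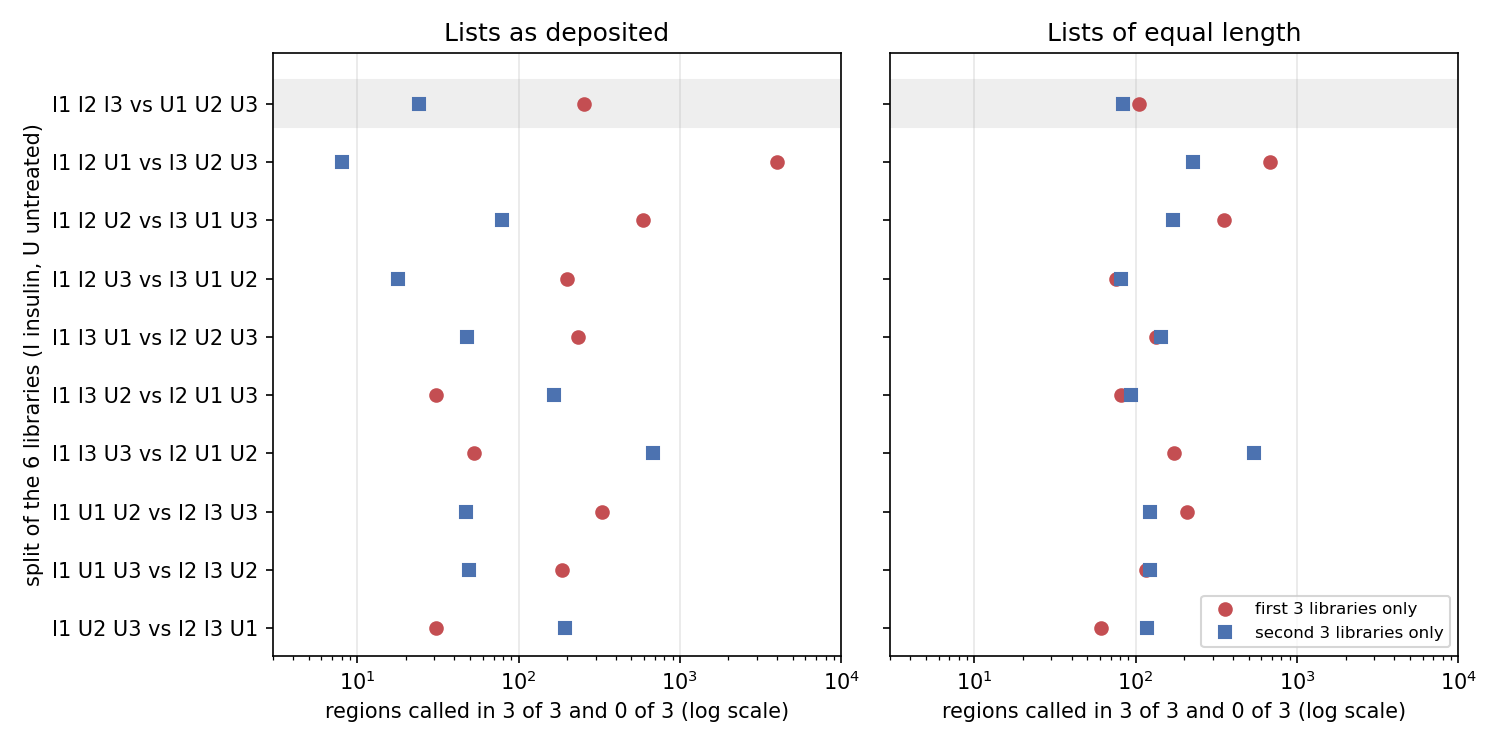
Number of regions called in all 3 libraries of one side and none of the other (horizontal, log scale) for each of the 10 splits of the 6 libraries (vertical; I, insulin; U, untreated), with the lists as deposited at left and with 26082 peaks per list at right. Circles are the first 3 libraries named and squares are the other 3; the shaded row is insulin against untreated, with 256 and 24 at left and 104 and 83 at right.

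The regions of either set were weak in their own lists. The median percentile of the 256 insulin-only regions was 31.9, 22.9 and 23.6 in insulin replicates 1, 2 and 3, and that of the 24 untreated-only regions was 30.6, 17.5 and 15.4. The insulin-only region with the highest mean percentile (80.3) lay on the unplaced contig chrUn_gl000220 at 117695 to 118394, a contig that carries ribosomal RNA genes. Its fold was low (2.67 to 3.42). The second was chromosome 9, 137261429 to 137262070, with folds of 11.4, 12.8 and 5.47 in insulin replicates 1, 2 and 3. The third was chromosome 5, 5828685 to 5829180, with folds of 11.4, 10.2 and 6.83, and then came chromosome 2, 238631895 to 238632722, with 7.88, 7.81 and 5.72. Chromosome 22, 50364324 to 50364779, had folds of 12.4, 6.43 and 4.65. The remaining 5 were chromosome 10, 74094497 to 74095319, chromosome 1, 206808526 to 206809152, chromosome 3, 43221551 to 43221940, chromosome 16, 87894894 to 87895761, and chromosome 17, 36858082 to 36859355, with folds between 3.51 and 11.7.

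Among the untreated-only regions, chromosome 9, 123814073 to 123814749, had the highest mean percentile (40.2), with folds of 4.07, 3.45 and 4.59 in untreated replicates 1, 2 and 3. Chromosome 1, 185317319 to 185317909, had 5.10, 3.80 and 3.34. Chromosome 17, 67014241 to 67014712, had 3.26, 3.70 and 4.87, and chromosome 2, 48678016 to 48678563, had 5.83, 3.25 and 3.06. The other six were chromosome 13, 46101944 to 46102407, chromosome 2, 39659850 to 39660362, chromosome 12, 45586109 to 45586617, chromosome 11, 34986464 to 34987069, chromosome 5, 59973665 to 59974330, and chromosome 7, 77388471 to 77389317, with folds between 2.54 and 6.05.

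The replicate 3 libraries stood apart from the rest in both treatments. They held 6319 regions that no replicate 1 or 2 library had. Of these, 2835 were called in insulin replicate 3 alone, 3227 in untreated replicate 3 alone and only 257 in both. They were mostly weak calls, since the median private peak stood at a percentile of 10.0 in the insulin list and 10.9 in the untreated list. Of the 6319 regions, 67.9% lay on chromosomes 2, 6, 14, 16, 17 and 20, against 34.1% of the regions shared by all 6 libraries. These 6 chromosomes were picked because the density of the 6319 regions there was more than 2 times that of the median chromosome. It was between 3.10 and 8.65 times there and at most 1.34 times on every other chromosome, a gap partly given by the choice. The crowding did not cover the whole of each chromosome. On chromosome 14 the bins of 10 Mb at 20000001 to 30000000 and 30000001 to 40000000 held 245 and 194 of these regions, and each bin from 50000001 to 110000000 held between 3 and 13. On chromosome 6 each bin from 70000001 to 110000000 held between 2 and 9, and on chromosome 17 the bins up to 20000000 held 7 and 5. Every bin of chromosome 20 held between 61 and 110, and those of chromosome 2 held between 14 and 160. On the chromosomes outside the 6 the median bin held 8 and the highest 48. Set against shared regions instead of chromosome length, the 6 chromosomes were not alike. Chromosome 17 held 3.94% of the regions of replicate 3 alone and 6.46% of the shared ones, and chromosome 16 held 5.89% and 5.21%. Chromosome 21, outside the 6, held 0.950% and 0.718%. The private regions of insulin replicate 3, taken alone, picked the same 6 chromosomes and had 66.4% on them. The untreated replicate 3 library had no part in that choice and had 69.8% of its private regions there. In the replicate 1 and 2 libraries that share was between 27.4% and 29.5%. The lists also differed in background, since 29.7% and 33.2% of the peaks of insulin and untreated replicate 3 lay at the lowest background of their list, against at most 1.29% in the other 4 lists. Whether replicate 3 was sequenced, controlled or processed differently is not given in the sources used here. Without both replicate 3 libraries, 2721 regions were found in both remaining insulin libraries and neither untreated one, and 392 showed the reverse. This total of 3113 compares with 3112 and 2707 for the other splits of these 4 libraries. With 31668 peaks per list the counts were 971 and 712, a total of 1683 against 2326 and 1616 for the other splits.

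**Figure D3:**
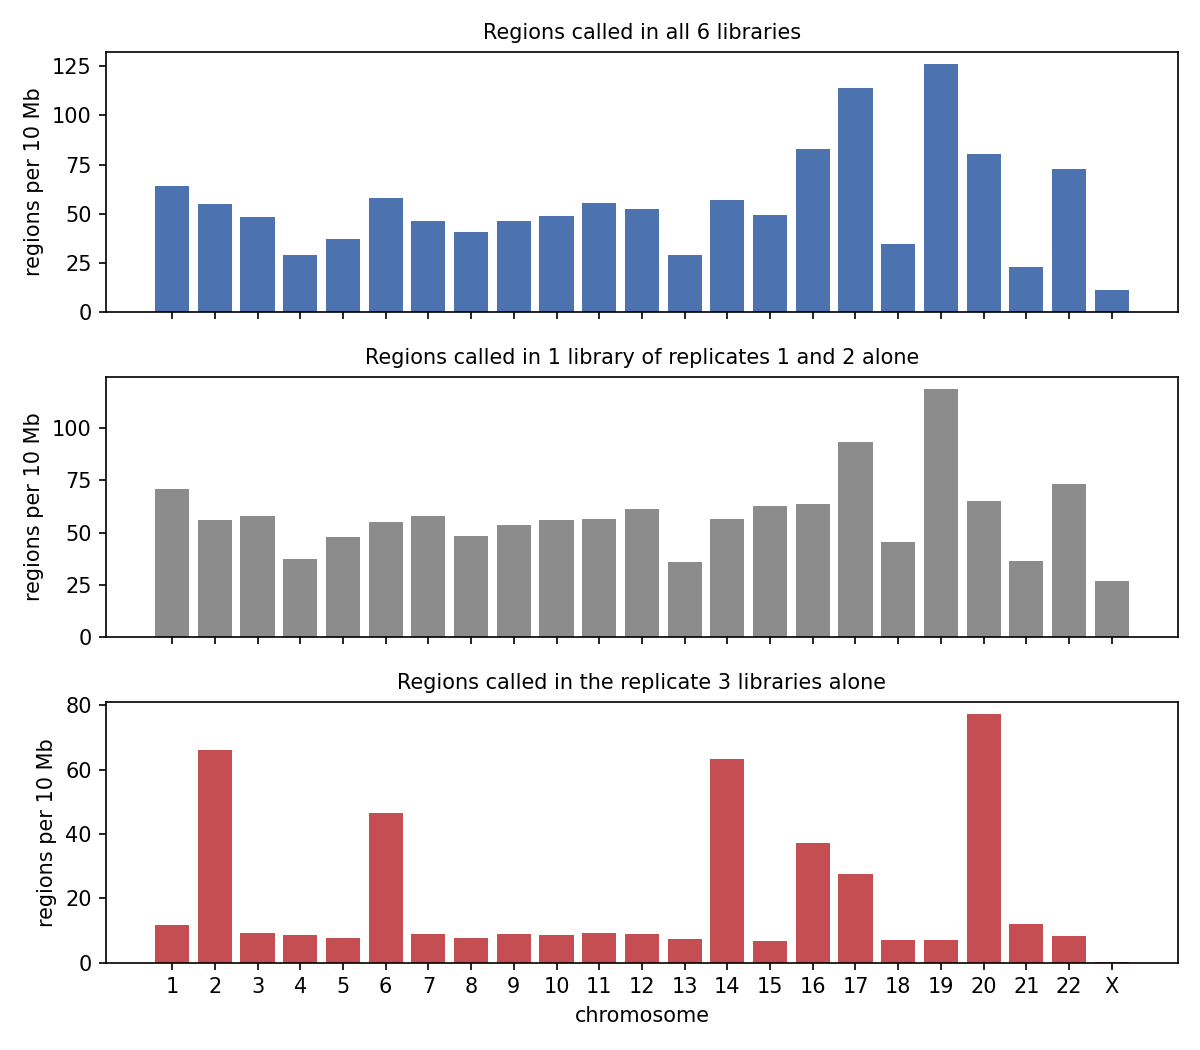
Regions per 10 Mb on each chromosome (horizontal) for regions called in all 6 libraries (top), in a single library of replicates 1 and 2 (middle) and in the replicate 3 libraries alone (bottom). Regions were divided by the number of 10 Mb bins with any region, part bins counted as whole. The bottom panel reaches 77.3 per 10 Mb on chromosome 20 and 66.2 on chromosome 2, against 7 on chromosome 19, where shared regions are densest.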

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

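The insulin-minus-untreated difference in peaks per library kept its sign in all 13 alternatives but ranged from 2078.5 to 12487 with each library left out, moving over 1.5 times for every library but untreated replicate 2; the replicate block and merging overlapping peaks (no peaks of a list overlap) cannot change it, and the exact permutation test over 20 assignments cannot go below 0.1. The overlap difference kept its negative sign in 12 alternatives, ranged from -0.0381 to 0.00107 with each library left out, and was positive only without untreated replicate 1; the cause was not tested. The count of regions in all 6 libraries stayed within 1.5 times in 9 alternatives. It was 7064 where each library had to cover 50% of the region, 25214 without replicate 3 in both treatments (4 libraries instead of 6), and 10476 without chromosomes 2, 6, 14, 16, 17 and 20 (less genome). The insulin-only and untreated-only counts depended most on the processing. Leaving out each library in turn gave 385 to 2382 insulin-only regions, moved by every library and most by insulin replicate 3, and 30 to 367 untreated-only regions, moved by every library but insulin replicate 3 and most by untreated replicate 3; fewer libraries make the rule easier to meet. With −log10 q of at least 5 the counts were 127 and 1, with equal lengths 104 and 83, without replicate 3 in both treatments 2721 and 392, and with equal lengths as well 971 and 712. With summits within 100 bp, untreated-only regions numbered 69, and without the 6 chromosomes insulin-only regions numbered 167; the cause of the first was not tested. The alternatives without replicate 3, without chromosomes or with union regions as peaks (a difference of 5824), and the one that left same-numbered pairs out, were chosen after seeing the data.

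Replicate numbers were not taken to pair the libraries. The deviations of same-numbered libraries from their group correlated at 0.101, 0.0606 and 0.266, and insulin replicate 2 correlated better with untreated replicate 1 (0.122). With the replicate block the peak difference stayed 6110 (two-sided exact sign-flip p = 0.25, the smallest possible with n = 3), the one-sided counts are 256 and 24 by construction, same-numbered libraries overlapped 0.0685 more than others of different treatment (the 2nd highest of 6 pairings), and the overlap difference was -0.00204 with same-numbered pairs left out. Equal lengths fix the peak number and give no difference in it. Alternatives for promoters, gene lists and motifs were not run.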

Other observations

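The median distance to the nearest region called in all 6 libraries was 14101 bp for the 256 insulin-only regions, 28888 bp for the 24 untreated-only regions and 31300 bp for the 23381 regions of 1 library, and 42.2%, 29.2% and 26.9% of them lay within 10 kb of one. The largest one-sided set among the splits was the 4022 regions of insulin replicates 1 and 2 and untreated replicate 1, the libraries with the 3 longest lists. Their median distance was 22235 bp, and 30.2% lay within 10 kb. These differences were not tested.

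All tests of explanations below were chosen after the results were seen. The first pattern is the excess of insulin-only over untreated-only regions, 256 against 24. Insulin lists that were longer on average are a candidate explanation for it. With lists of equal length the larger count was 1.25 times the smaller, but this cannot decide the question. The cut removes the weakest peaks of the longer lists. Only 16.4% and 8.59% of the 256 regions stood above the list median in insulin replicates 1 and 2, so most would drop out whatever their cause. Peaks with −log10 q of at least 5 gave 127 against 1, but −log10 q depends on the depth of the library. An effect of insulin on FoxK1 occupancy cannot be told apart from differences between libraries. Equal lists gave 187 one-sided regions for the real split. They gave between 156 and 278 for the other splits that keep the replicate 3 libraries apart. The highest total, 902, came from a split with both replicate 3 libraries on one side, so it does not bear on insulin. Of the 10 splits of the lists as deposited, 6 gave at least the 280 regions of the real one, the highest other 4030, and 10 splits are too few for a share under 0.05. A split with many times the real count points to a structure of the libraries other than treatment.

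The second pattern is the crowding of regions found in replicate 3 alone on all or parts of chromosomes 2, 6, 14, 16, 17 and 20. Insulin is argued against, since the same 6 chromosomes were picked from the private regions of insulin replicate 3 alone, and the untreated replicate 3 library had 69.8% of its private regions on them, against at most 29.5% in any replicate 1 or 2 library. A background wholly blind to copy number is argued against by the share of these peaks at the floor. That share was at least 23.6 percentage points lower in 10 Mb bins of high background than in bins of low background. The median background of these peaks rose little, however. It was 2.88 in high bins against 2.66 in low bins in insulin replicate 3, and 3.52 against 3.39 in untreated replicate 3. A background that registers copy number only in part stays open. Extra copies of chromosomes in HepG2 may contribute, since across 283 bins the number of these regions rose with the background of the other 4 libraries (Spearman rho 0.563, across bins that are not independent, against at most 0.292 for regions private to any of those libraries). The rise did not hold everywhere. The 2 crowded bins of chromosome 14 had backgrounds of 2.39 and 2.36 times the median bin. On chromosome 2, however, the bins with 160 and 120 of these regions had 1.26 and 1.25 times, and a bin with 38 had 1.57 times. The fullest bin outside the 6 chromosomes, with 48 on chromosome 21, had 0.484 times. Chromosome 19 had a high background (1.21 times the median) and no crowding (0.783 times). Fewer immunoprecipitated fragments in replicate 3 stay open, because total read numbers are not given. Its lowest background per kb goes against them, taking the shortest peak of each list as a stand-in for fragment length. It was 9.95 and 12.1 fragments, against 5.02 to 7.67 in the other lists. The lower replicate 3 value was 1.30 times the highest of the others. Replicate 3 had the fewest peaks and the lowest median summits, 21 and 22 fragments against 27 to 43. These also depend on how strongly sites were enriched and do not measure depth alone.

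A difference in how the replicate 3 libraries were sequenced, controlled or called was not tested and stays open, and it bears on the regions of replicate 3 alone and on each background comparison above. The 2 crowded bins of chromosome 14 held 91 and 75 regions called in all 6 libraries.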
